A study of Rattus norvegicus with 10 samples.

How the data were processed

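Bulk RNA sequencing was done on L6 dorsal root ganglia of rats given PBS (5 samples) or the divalent siRNA SCN9A_2544 (5 samples, 0.75 mg) through an intrathecal lumbar catheter, in 30 to 45 µL. Per the labels' protocols, RNA was extracted with phenol and chloroform and purified on silica membrane plates, poly(A) RNA was selected, libraries were prepared with the NEBNext Ultra II RNA kit, and paired reads of 150 bases were sequenced on a NovaSeq instrument. Poly(A) selection enriches polyadenylated transcripts, so other transcripts may be poorly measured.

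The authors deposited a table of estimated counts per gene, not normalized, with 1 column per library and no pooled column. Between 11.6% and 12.4% of the values in a library were not whole numbers, which a count that shares reads between features gives. The submitters' processing notes name STAR 2.7.10a, DESeq2 1.44.0 and the rat build mRatBN7.2, with no role given. The program that estimated the counts, the annotation release, the strand setting and any filter are not given in the sources used here. The table pairs Ensembl gene identifiers with gene names, and these names were used as given. Another table of rat gene names, on another assembly, was not used here, and no coordinates are reported. Among the tested genes 159 names belonged to more than 1 identifier, and 1218 identifiers had no symbol.

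The design written before the data were examined assumed raw counts. Because the values were estimated counts, they were rounded to whole numbers before the count tests, and the test stayed as planned. Samples were grouped by the labels' titles, and the only comparison was SCN9A_2544 against PBS, with all 10 libraries in the fit. The labels give separate samples and a random allocation of animals, without saying that each sample is 1 animal, so p-values measure the spread between these samples, part of which may be technical. No library batch is given in the labels. No non-targeting siRNA group was analysed here, so effects of the siRNA sequence and of dosing with any siRNA are not separated by this comparison. A chi-square per gene between every pair of the 10 libraries (45 pairs) ran from 7.80 to 218, so no pair agreed within sampling noise. This shows that no library repeats another, but not that each came from its own animal. Each library was counted as 1 replicate.

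Genes with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 15186 of 30560 genes. Libraries were scaled with TMM factors, and edgeR 4.0.16 in R 4.3.3 was used for the quasi-likelihood F-test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are TMM-scaled, and log2 CPM values use a prior count of 2. Gene lists were tested with camera from limma 3.58.1 on log2 CPM, with a preset correlation of 0.01, for lists with at least 3 tested members, and with Benjamini-Hochberg adjustment over the 34 lists. A preset correlation takes little account of genes that vary together between ganglia, so camera with an estimated correlation and fry, in its directional and mixed forms, are given beside it. Values of a single measure per library were compared with two-sided exact permutation tests over all splits into 5 and 5, whose smallest p is 0.00794. Correlations over libraries used 1e+05 permutations.

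The lists covered sodium channels, pan-neuronal genes, 4 kinds of sensory neuron, pain-related receptors and channels, the opioid and cannabinoid system, nerve injury genes, satellite glia, Schwann cells, macrophages, lymphocytes, neutrophils, interferon-stimulated genes, nucleic acid sensors, inflammatory mediators, RNA interference machinery, endothelial cells, fibroblasts, central glia, muscle, fat, blood, cholesterol synthesis, p53 targets, the unfolded protein response, immediate early genes, heat shock genes, lysosomes, the cell cycle, sex-linked genes, and mitochondrially encoded and nuclear genes of oxidative phosphorylation. They named 612 genes, of which 581 had a row under that name and 522 were tested, while the rest were not analysed here. The rule for the genes named in the text was fixed before the data were examined. It takes every tested sodium channel gene, the 12 higher and 12 lower genes with the smallest p among those past the threshold, up to 4 members with the smallest p of each list described, and, where fewer than 10 genes pass, the 10 genes with the smallest p. Some genes that this rule takes are not reported here.

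The edgeR procedure was tested on simulated data for this comparison, with counts for the 15186 tested genes drawn from the real means, library sizes and dispersions, and 200 genes changed by known folds. It recovered 4% of the 50 genes changed 1.5-fold, 40% of those changed 2-fold, 80% of those changed 3-fold and 88% of those changed 4-fold, with 2 false calls among 108. Most changes of 2-fold or smaller were therefore missed at the depth, spread and number of libraries simulated, which were not varied. Genes were drawn independently of each other, so variation shared between genes was not simulated. Recovery with fewer than 200 changed genes was not simulated either.

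Alternatives fixed before the data were examined were DESeq2's size factors, upper-quartile scaling and plain library size, no filter and a filter at CPM above 1, DESeq2 1.42.0, limma voom with library quality weights, robust dispersion, the replicate number as a block, the pan-neuronal mean or the Schwann cell and myelin mean as a covariate, other thresholds, other set tests, other reference lists for Scn9a, and each library left out in turn. Added after seeing the data were a fit without the 3 libraries of lowest pan-neuronal mean, an exact permutation test of each list mean, both covariates together and a fit without mitochondrially encoded genes.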

Results

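Gene expression was measured by RNA sequencing in L6 dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, of Sprague Dawley rats aged 7 to 8 weeks. All animals carried a catheter in the lumbar intrathecal space. There were 5 samples from rats given phosphate-buffered saline (PBS) through it and 5 samples from rats given 0.75 mg of SCN9A_2544, a divalent small interfering RNA (siRNA) directed at Scn9a. Dosing took place 5 days after the catheter surgery, and the labels give 14 days as the timepoint of every sample, without saying whether these days count from surgery or from dosing. Each of the 10 libraries came from 1 labelled sample, and animals had been allocated to the groups at random, per the labels. Library totals ran from 11832376 to 15420006 estimated counts, and 15186 of the 30560 genes in the table had enough counts to be tested. The median standard error of a log2 fold change over these genes was 0.22, and the biological coefficient of variation was 30.0%.

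The first question, given by the series title, was how far the siRNA lowered its target. Scn9a (ENSRNOG00000006639) encodes Nav1.7, a voltage-gated sodium channel of peripheral sensory neurons. It stood at 175 ± 50.2 CPM, counts scaled to a common library size, in PBS ganglia and at 85.4 ± 23.9 CPM in SCN9A_2544 ganglia (SD, n = 5 each). Every treated library, at 44.6 to 103 CPM, lay below every PBS library, at 132 to 257 CPM. Scn9a fell by 1.05 on the log2 CPM scale between the group means, with a two-sided exact permutation p = 0.00794, the smallest that the splits of 10 libraries into 5 and 5 allow. Set against the mean of 20 pan-neuronal genes in the same library, Scn9a fell by 1.16 on the log2 scale, a change of -55.2%, with the same exact permutation p = 0.00794. The pan-neuronal mean itself differed by 0.11 on the log2 scale (exact permutation p = 0.786), which is less than its spread between libraries.

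In the edgeR fit over all genes the log2 fold change of Scn9a was -1.03 (SE 0.25, 95% interval -1.57 to -0.49). Its adjusted p was 0.963 over all genes tested and 0.0188 adjusted over the list alone, the list being the 14 sodium channel genes. With the pan-neuronal mean as a covariate the edgeR log2 fold change was -1.14 (SE 0.13) with an adjusted p = 0.0214 over all genes, and with the Schwann cell and myelin mean it was -1.16 (SE 0.13) with an adjusted p = 0.0156. The Scn9a estimates held fractions of a count in all 10 libraries, as estimates that divide reads between features do.

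**Figure D1:**
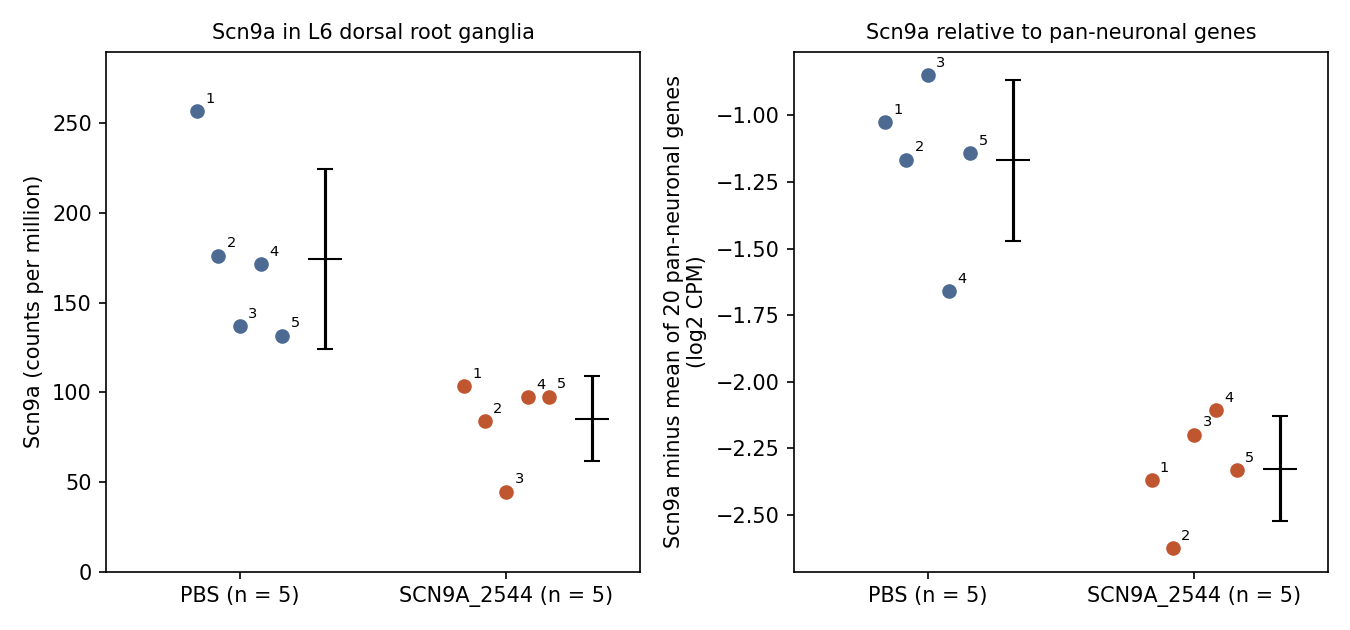
Scn9a in each library, as CPM (left, linear axis from 0) and as log2 CPM minus the mean log2 CPM of 20 pan-neuronal genes (right), for 5 PBS and 5 SCN9A_2544 libraries. Points are libraries labelled by replicate number and bars are the mean and SD, and all treated libraries (44.6 to 103 CPM) lie below all PBS libraries (132 to 257 CPM).

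The libraries differed in their content of neurons and Schwann cells, the glia that wrap peripheral axons, and this variation ran across the groups. The pan-neuronal mean ranged from 7.95 to 9.08 log2 CPM in PBS libraries and from 7.68 to 9.06 in treated libraries. The first principal component, holding 43.5% of the variance, followed the pan-neuronal mean over the 10 libraries (Pearson r = -0.99, permutation p = 5e-05, Spearman rho = -0.99, permutation p = 4e-05). The pan-neuronal mean ran against the mean of the Schwann cell and myelin markers (r = -0.96, permutation p = 4e-05, rho = -0.95, permutation p = 0.00019). Without the 2 libraries farthest from the median these r values were -0.99 and -0.93, and adjusted over the 2 relations computed the p-values for r were both 5e-05, while those for rho were 8e-05 and 0.00019. The Schwann cell and myelin mean was 8.71 ± 0.82 log2 CPM in PBS and 8.49 ± 0.70 in treated ganglia (SD, n = 5 each, exact permutation p = 0.643).

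**Figure D2:**
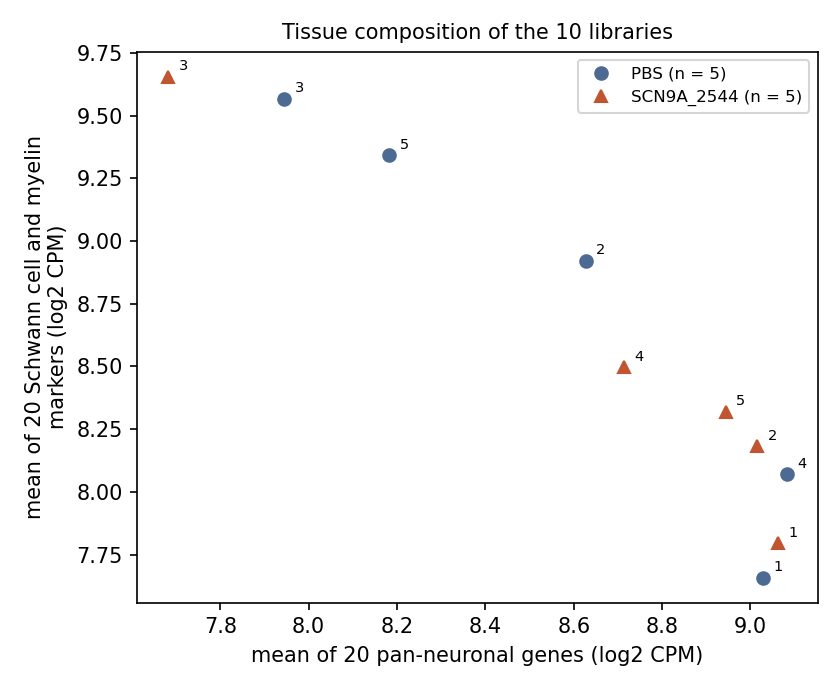
Mean log2 CPM of 20 Schwann cell and myelin markers (vertical axis) against the mean log2 CPM of 20 pan-neuronal genes (horizontal axis) in the 10 libraries, labelled by replicate number, with circles for PBS and triangles for SCN9A_2544. Both groups spread along the same line, and SCN9A_2544 replicate 3 has the lowest pan-neuronal mean, 7.68.

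The second question, stated in the series design, was the specificity of the siRNA, beginning with the gene family of its target. Of the 13 tested sodium channel genes other than Scn9a, 0 passed an adjusted p of 0.05 by edgeR, 0 by DESeq2 and 0 adjusted over the list alone, and 0 had an unadjusted p under 0.05 by edgeR. The nociceptor channels Scn10a, encoding Nav1.8, and Scn11a, encoding Nav1.9, had log2 fold changes of 0.31 (95% interval -0.42 to 1.04) and 0.08 (-0.62 to 0.77). Scn10a stood at 345 ± 162 CPM in PBS and 427 ± 128 CPM in treated ganglia (SD, n = 5 each). Scn8a, which encodes the axonal channel Nav1.6, had a log2 fold change of 0.45 (-0.64 to 1.54) and Scn1a one of 0.01 (-0.77 to 0.78). Scn7a, the most abundant family member and a gene also expressed in glia, had the lowest value after Scn9a, -0.50 (-1.15 to 0.15). Scn7a also belongs to the list of Schwann cell and myelin markers, and without the 3 libraries of lowest pan-neuronal mean, a choice made after seeing the data, its log2 fold change was 0.01.

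The alpha subunit genes Scn2a, Scn3a and Scn4a had log2 fold changes of -0.08, 0.29 and 0.24. The beta subunit genes Scn2b, Scn3b and Scn4b had values of 0.16, 0.11 and 0.10. Scn1a lay so close to 0 that its sign turned under DESeq2's size factors and upper-quartile scaling and in 15 of the 24 alternatives in all. Signs also turned for Scn4b in 8 of the 24, Scn11a in 4, Scn2a in 3, Scn3b in 2, and Scn2b and Scn7a in 1 each. The intervals were wide: that of Scn8a reached -0.64 and that of Scn2a -0.66, so a reduction of that size was not excluded at this number of libraries. The genes of this family are paralogs, and the division of shared reads among them was made before deposit, so their single values carry that uncertainty.

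**Figure D3:**
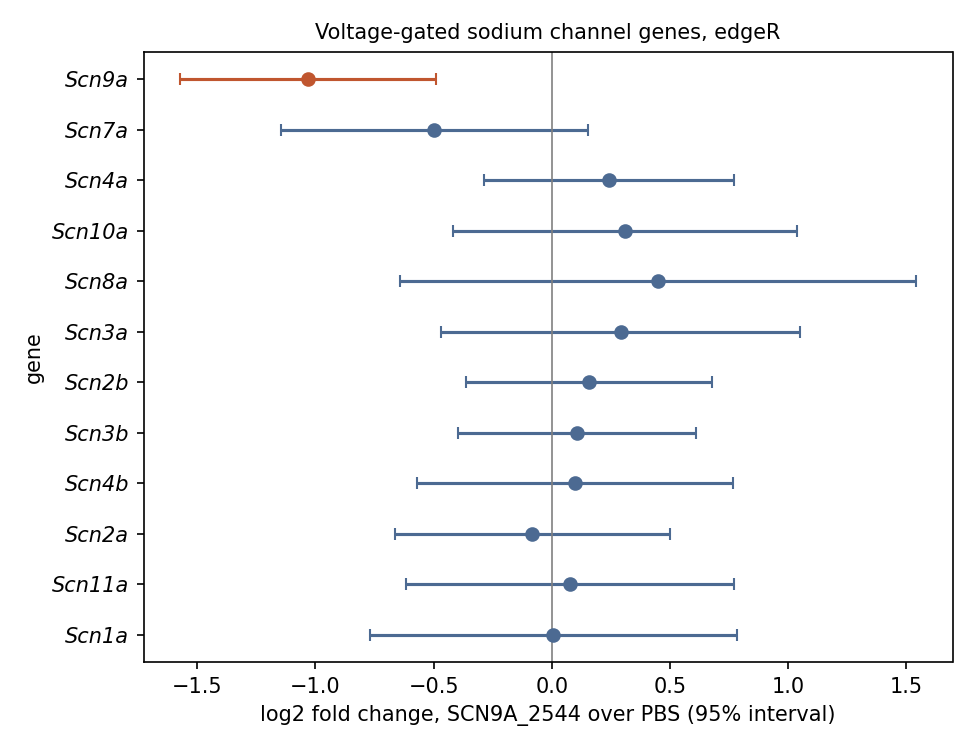
Log2 fold change of SCN9A_2544 over PBS for 12 sodium channel genes, from edgeR's quasi-likelihood test, with 95% intervals. The interval of Scn9a runs from -1.57 to -0.49, and those of the other 11 genes shown include 0.

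Across the whole transcriptome, edgeR's quasi-likelihood test called 0 genes higher and 0 genes lower at an adjusted p of 0.05. An unadjusted p under 0.05 was reached by 642 genes, 379 higher and 263 lower in treated ganglia, against 759 expected with no effect. Of 100 drawn splits of the libraries into 5 and 5, the real one included, 35 gave at least 642 such genes. Groups did not overlap for 101 genes (0.665%), against 0.794% by chance. DESeq2 called 17 genes, 16 higher and 1 lower, with 967 genes at an unadjusted p under 0.05. limma voom with library weights called 1 gene, ENSRNOG00000070035, lower in treated ganglia, with 3175 genes at an unadjusted p under 0.05. By edgeR, ENSRNOG00000070035, named here after its values were seen, had a log2 fold change of -2.67 (SE 1.13) and an adjusted p of 0.963. The count of calls by edgeR was 1 without SCN9A_2544 replicate 2 (Stac2, adjusted p = 0.0396) and 1 without SCN9A_2544 replicate 3 (ENSRNOG00000070035). The 642 became 1642 without PBS replicate 4, 385 without PBS replicate 5, 406 without SCN9A_2544 replicate 1 and 991 without SCN9A_2544 replicate 3.

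The 10 genes with the smallest p were all higher in treated ganglia and did not pass the edgeR threshold, with adjusted p-values of 0.412 for the first 2 and 0.812 for the others, while DESeq2 called all 10. Stac2 (ENSRNOG00000004805), an adaptor protein that binds voltage-gated calcium channels, stood at 1.60 ± 0.50 CPM in PBS and at 16.6 ± 13.2 CPM in treated ganglia (SD, n = 5 each), with a log2 fold change of 3.37 (SE 0.51). ENSRNOG00000068602, which carries no symbol in the table, had a log2 fold change of 1.68 (SE 0.27). Genes of immune cells and their signals among the 10 were C1qa, a chain of complement C1q, at 1.03 (SE 0.20), Lilrb4, an inhibitory leukocyte receptor, at 1.75 (SE 0.37), Il1rap, a co-receptor for interleukin-1, at 0.75 (SE 0.16), and Ssc5d, a scavenger receptor family protein, at 0.78 (SE 0.16). The others were Ecel1, an endopeptidase of injured neurons, at 2.28 (SE 0.46), Egr1, an immediate early transcription factor, at 1.34 (SE 0.28), Tgm1, a transglutaminase, at 3.86 (SE 0.82), and Postn, the matrix protein periostin, at 1.50 (SE 0.32). Scn9a ranked 18th by p in this fit. Of the 34 gene lists fixed before the data were examined, 5 passed an adjusted p of 0.05 in limma's camera test with a preset correlation, and 0 passed with an estimated correlation or with fry's directional test, while fry's mixed test, which takes changes in either direction, passed 1, macrophage markers (adjusted p = 0.047). The count of 5 became 8 without PBS replicate 1, 10 without PBS replicate 5 and 10 without SCN9A_2544 replicate 3. Other drawn splits of the libraries into 5 and 5 gave a median of 12 lists, so small p-values of this test carry little weight here.

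Genes that sensory neurons express after nerve injury were higher in treated ganglia by the first of these tests. The camera adjusted p was 1.28e-07 with the preset correlation, and adjusted p = 0.321 with an estimated correlation. The mean of the 20 tested nerve injury genes was 3.21 ± 0.15 log2 CPM in PBS and 3.98 ± 0.63 in treated ganglia (SD, n = 5 each), and 18 of the 20 had a log2 fold change above 0. Over all genes tested 0 members passed by edgeR, and adjusted over the list alone 7 were higher and 0 lower. DESeq2 called 3 members of the list over all genes, all higher: Ecel1 (adjusted p = 0.0032), and Vip and Crisp3, named after their values were seen, whose counts were too low for the edgeR test. Among the 4 with the smallest p, Ecel1 stood at 1.87 ± 0.67 CPM in PBS and 9.13 ± 6.05 CPM in treated ganglia, and the transcription factor Jun at 124 ± 13.0 CPM and 206 ± 54.8 CPM (SD, n = 5 each). The neuropeptide gene Npy stood at 2.58 ± 1.45 CPM in PBS and 31.0 ± 40.0 CPM in treated ganglia, and the galanin gene Gal at 1.82 ± 0.62 CPM and 16.6 ± 24.9 CPM (SD, n = 5 each). The spread within the treated group was wide: Npy ranged from 1.98 CPM in replicate 3 to 98.5 CPM in replicate 4, and Gal from 1.63 to 60.6 CPM in the same libraries. An exact permutation test of the list mean gave p = 0.0317, or 0.337 adjusted over the lists.

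Macrophage markers were also higher in treated ganglia by the camera test with the preset correlation. The camera adjusted p was 5.22e-10, and adjusted p = 0.473 with an estimated correlation. The mean of the 23 tested markers was 3.77 ± 0.19 log2 CPM in PBS and 4.27 ± 0.40 in treated ganglia (SD, n = 5 each), and 21 of the 23 lay above 0. Over all genes tested 0 members passed by edgeR and 1, C1qa, by DESeq2 (adjusted p = 0.0124), and adjusted over the list alone 9 were higher and 1 was lower by edgeR. The complement genes C1qa, C1qb and C1qc had log2 fold changes of 1.03, 0.99 and 0.96, C1qa standing at 28.8 ± 5.74 CPM in PBS and 58.8 ± 15.4 CPM in treated ganglia (SD, n = 5 each). Lyve1, a marker of some resident tissue macrophages, was the 1 lower member, with a log2 fold change of -0.78. The exact permutation p of the list mean was 0.0238, or 0.337 adjusted over the lists. SCN9A_2544 replicate 4 had the highest mean of this list, 4.84, as it had for nerve injury genes. SCN9A_2544 replicate 2, at 3.85, lay below PBS replicates 2 and 4, at 3.98 and 3.88. The difference of the list mean was 0.50 with all libraries and as low as 0.36 with 1 library left out.

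A further 2 lists were higher by camera with the preset correlation. With an estimated correlation the adjusted p was 0.321 for satellite glia markers and 0.643 for immediate early genes. Satellite glia are the cells that ensheathe the neuronal cell bodies, and the mean of their 14 markers was 6.09 ± 0.14 log2 CPM in PBS and 6.35 ± 0.14 in treated ganglia (SD, n = 5 each). Of these 14, 12 lay above 0, and 0 passed by edgeR, over all genes tested or adjusted over the list alone. Their 4 smallest p-values belonged to the endothelin receptor gene Ednrb, Ptprz1, the potassium channel gene Kcnj10 and the connexin gene Gja1, with log2 fold changes of 1.07, 0.42, 0.49 and 0.48. The camera adjusted p of this list was 0.00872, and the exact permutation p of its mean was 0.0397, or 0.337 adjusted over the lists. Immediate early genes, which respond within minutes to stimulation, had 16 of 20 tested members above 0, with 0 past the threshold over all genes by edgeR, 1 by DESeq2 (Egr1, adjusted p = 0.0179) and 3 higher by edgeR adjusted over the list alone. Egr1, Jun, Fosb and Fos had log2 fold changes of 1.34, 0.74, 1.41 and 1.57, Fos not passing adjusted over the list alone. The difference of the list mean was 0.43 on the log2 scale and 0.19 without SCN9A_2544 replicate 3. With all libraries its exact permutation p was 0.167, or 0.81 adjusted over the lists. The camera adjusted p of this list was 1.83e-05, and the call was also lost with limma voom and library weights (adjusted p = 0.278).

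The list of mitochondrially encoded genes was lower by camera with the preset correlation. The camera adjusted p was 2.19e-07, and adjusted p = 0.643 with an estimated correlation. All 13 tested members lay below 0, and 0 passed by edgeR, over all genes tested or adjusted over the list alone. Mt-nd6, Mt-nd4, Mt-nd2 and Mt-nd1, subunits of respiratory complex I, had log2 fold changes of -0.51, -0.61, -0.61 and -0.50. The mean of the list was 10.81 ± 0.40 log2 CPM in PBS and 10.46 ± 0.12 in treated ganglia (SD, n = 5 each), and PBS replicate 4, at 10.22, lay below every treated library. The difference of the list mean was -0.34 with all libraries and -0.17 without the 3 libraries of lowest pan-neuronal mean. With all libraries its exact permutation p was 0.119, or 0.675 adjusted over the lists. The nuclear genes of oxidative phosphorylation differed by -0.07 in their mean, with a camera adjusted p of 0.0922, and this list passed, lower, in 10 of 25 alternatives, among them each composition covariate and the fits without PBS replicates 2, 3 or 5 or SCN9A_2544 replicates 1, 2 or 5.

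**Figure D4:**
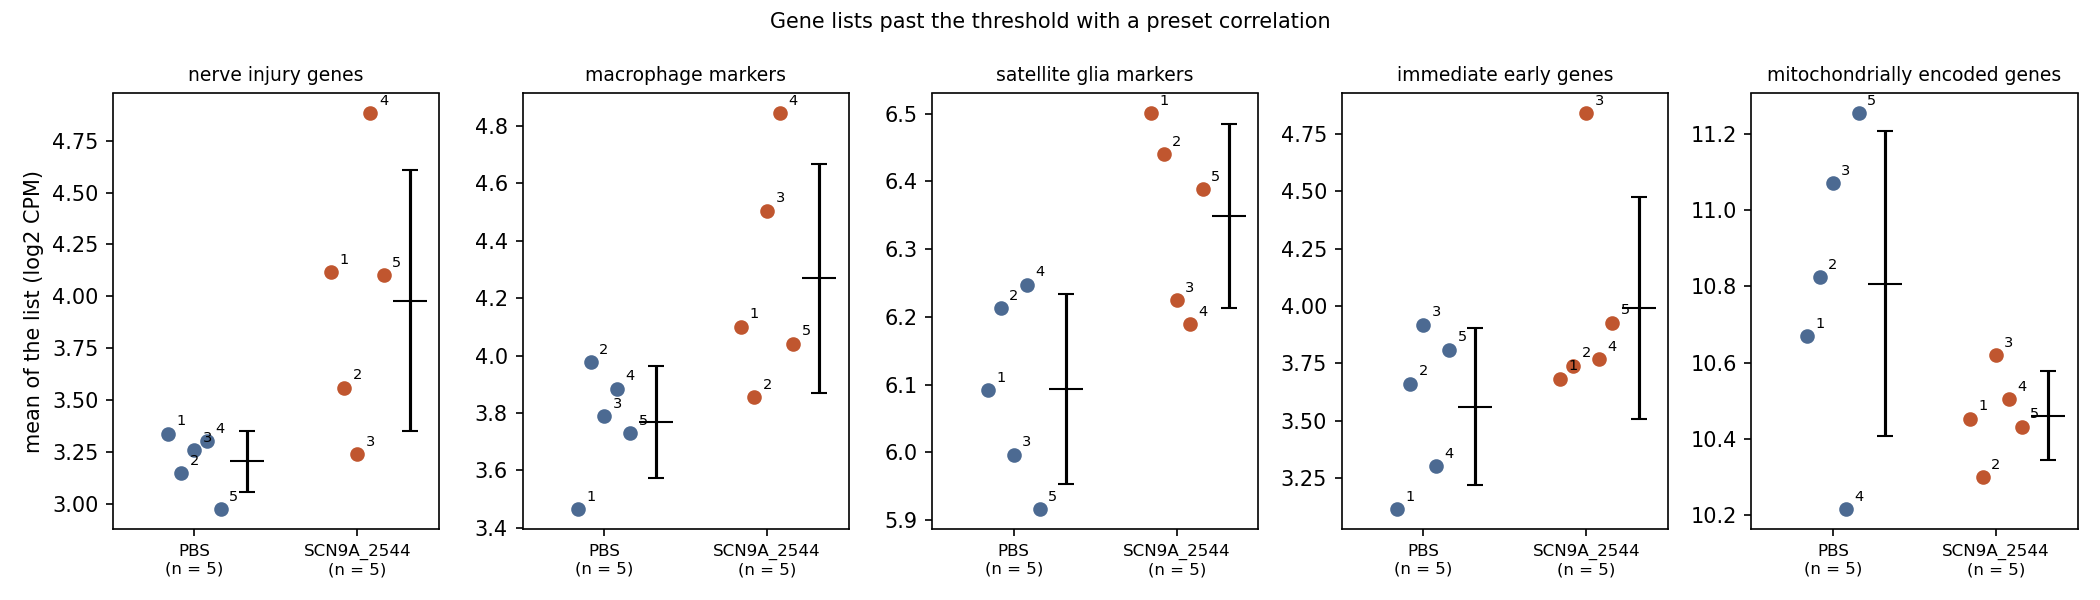
Mean log2 CPM of the 5 lists that passed limma's camera test with a preset correlation, in 5 PBS and 5 SCN9A_2544 libraries. Points are libraries labelled by replicate number and bars are the mean and SD; the vertical axes differ between panels, and SCN9A_2544 replicate 4 has the highest nerve injury mean, 4.88.

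Lists that bear on a response to foreign RNA did not pass camera with the preset correlation in all 10 libraries, and 2 of the 4 passed in some alternatives. The 30 interferon-stimulated genes tested split into 14 above and 16 below 0, with a mean difference of -0.10 on the log2 scale and a camera adjusted p of 0.219. Bst2, Cxcl10, Oasl2 and Isg15, with the smallest p of these, had log2 fold changes of -0.41, 0.76, -0.25 and -0.61. The nucleic acid sensors differed by 0.12 (adjusted p = 0.275), with Unc93b1, Tlr9, Sting1 and Myd88 at 0.39, 0.53, 0.35 and 0.19. Inflammatory cytokines and mediators differed by 0.19 (adjusted p = 0.600), with the chemokine genes Cxcl9 and Cxcl16 at 1.57 and 0.45. The RNA interference machinery differed by 0.01 (adjusted p = 0.871), with Tnrc6a, Xpo5, Mov10 and Tnrc6b at -0.21, 0.24, 0.34 and -0.31. In these 4 lists 0 members passed by edgeR, over all genes or adjusted over the list alone. The interferon-stimulated list passed, lower, in 3 of 25 alternatives: limma voom with library weights, without SCN9A_2544 replicate 3, and without the 3 libraries of lowest pan-neuronal mean. Inflammatory mediators passed, higher, in 2 of 25, with no filter and without those 3 libraries.

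Lists of sensory neuron types did not pass in all 10 libraries either. The mean differences on the log2 scale were 0.14 for peptidergic nociceptor markers (camera adjusted p = 0.614), 0.13 for non-peptidergic nociceptor markers (0.614), 0.05 for large-diameter afferent markers (0.869) and -0.03 for C-low-threshold mechanoreceptor markers (0.845). Pain-related receptors and channels other than sodium channels differed by 0.20 (adjusted p = 0.131), with 23 of 27 members above 0, among them the calcium channel subunit gene Cacna2d1 at 0.84 and the bradykinin receptor gene Bdkrb2 at 0.52. The heat receptor gene Trpv1, a peptidergic marker, had a log2 fold change of 0.32, and Kit and Adcyap1 of the same list had 0.54 and 0.63. In these lists 0 members passed by edgeR, over all genes or adjusted over the list alone. The opioid and cannabinoid system differed by 0.16 (adjusted p = 0.766), with Mgll, Oprd1, Faah and Pnoc at -0.45, 0.78, 0.24 and 0.71. The 20 pan-neuronal genes had a camera adjusted p of 0.649 and the whole sodium channel list one of 0.869. Peptidergic nociceptor markers and pan-neuronal genes each passed, higher, in 2 of 25 alternatives, limma voom with library weights and without SCN9A_2544 replicate 3. The pain-related list passed, higher, in 6 of 25, among them these 2 and the fits without PBS replicate 1, without PBS replicate 4 and without the 3 libraries of lowest pan-neuronal mean.

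Markers of other cell types that a dissected ganglion could hold had camera adjusted p-values above 0.05 in all 10 libraries. The mean differences on the log2 scale were -0.22 for Schwann cell and myelin markers (adjusted p = 0.0979), 0.31 for fibroblast and extracellular matrix genes (0.275), -0.01 for endothelial and mural cell markers (0.766), -0.04 for neutrophil markers (0.845), 0.06 for T and B lymphocyte markers (0.869), -0.13 for erythroid and blood genes (0.854), 0.02 for central nervous system glia markers (0.869), 0.09 for skeletal muscle markers (0.956) and -0.55 for adipocyte markers (0.144). Within these lists Postn was higher and the fatty acid binding gene Fabp4 lower, at -1.41, adjusted over the list alone, and DESeq2 called Postn over all genes. With limma voom and library weights the Schwann cell, adipocyte, endothelial and neutrophil lists passed, all lower. Schwann cell markers also passed, lower, without PBS replicate 1, PBS replicate 4 or SCN9A_2544 replicate 3, and endothelial markers without PBS replicate 1. Without PBS replicate 5 the neutrophil, erythroid and lymphocyte lists passed, lower, and the fibroblast list, higher. These 4 lists and the adipocyte list also passed in the same directions without the 3 libraries of lowest pan-neuronal mean, the fibroblast list with the Schwann cell covariate, alone or with the pan-neuronal one, and the adipocyte list with no filter.

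Lists of general cell state had camera adjusted p-values above 0.05 in all 10 libraries as well. The mean differences were 0.14 for p53 targets and apoptosis (adjusted p = 0.325), 0.02 for the unfolded protein and integrated stress response (0.956), 0.03 for heat shock genes (0.944), 0.15 for cell cycle genes (0.440), -0.04 for cholesterol biosynthesis (0.600), 0.10 for lysosome genes (0.277) and -0.11 for sex-linked genes (0.325). Cell cycle genes passed in 3 of 25 alternatives and in both directions, lower with limma voom and library weights and without the 3 libraries of lowest pan-neuronal mean, and higher without PBS replicate 3. The p53 list passed, higher, in 2 of 25, with both covariates and without those 3 libraries. Ctss, a lysosomal protease of antigen-presenting cells, was higher adjusted over the list alone, at 0.89, with 21.6 ± 3.25 CPM in PBS and 40.0 ± 12.2 CPM in treated ganglia (SD, n = 5 each). Cdkn1a and Bak1 of the p53 list had log2 fold changes of 0.56 and 0.47, and Idi1 and Hmgcs1 of the cholesterol list had -0.56 and -0.39. The camera direction was down with a mean difference and a median member above 0 for the large-diameter afferent, sodium channel, RNA interference and heat shock lists. The median member lay below 0 with a mean difference above 0 for inflammatory mediators (-0.03) and lymphocyte markers (-0.13).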

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

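The tests of nociceptor share, paralog reads (both sets of genes), neuron to Schwann cell ratio, the single library, blood and neuron share given here were chosen after the result was seen, while the splits of the libraries and the covariates from 7 other lists were set before. Of 118 group values examined for a library far from its group, 11 stood out, where chance gives about 5.9. The gap to the nearest library, as a share of the group's range, was above the critical value of 0.71 in each. SCN9A_2544 replicate 3 accounted for 8 of them. It had the lowest values of the group for sodium channel genes (gap 0.714), pan-neuronal genes (0.748), C-low-threshold mechanoreceptor markers (0.763), heat shock genes (0.839), nuclear genes of oxidative phosphorylation (0.921) and Scn9a (0.750). It had the highest values for endothelial and mural cell markers (0.727) and immediate early genes (0.789). PBS replicate 1 was lowest for nucleic acid sensors (0.780), PBS replicate 5 was highest for Tgm1 (0.768), and PBS replicate 4 had the lowest library total (0.745).

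For the 0 genes that edgeR called, a count of splits decides nothing, since each of the 100 splits into 5 and 5 that were drawn gives at least 0; the highest other split gave 3156 genes. Chance could not be excluded for the other counts of calls. At least the 5 lists of the camera test were reached by 89 of 100 splits, the real one included, with up to 23 lists. The median of the other splits was 12 lists. A call by camera with the preset correlation is thus little evidence of a difference between the groups. At least the 17 genes of DESeq2 were reached by 8 of 50 splits, the real one included, with up to 4209 genes. At least the 1 gene called with the pan-neuronal covariate, Scn9a, was reached by 9 of 100 splits, the real one included, with up to 520 genes. That count takes any gene, so it decides nothing about Scn9a by itself. Such numbers of calls may come from a structure of the samples that crosses the groups. By edgeR, the splits that gave 3156 and 1251 genes without a covariate gave 0 with the pan-neuronal covariate. Differences in neuronal content may thus account for the calls in those splits. For the counts of lists and of DESeq2 calls this was not tested. The fit that gave up to 520 genes already held the pan-neuronal mean, and the same split gave 0 genes without it, so that count has another source.

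Scn9a passed the threshold over all genes only in the 3 fits with a composition covariate among the alternatives run. When 7 lists not tied to neurons or Schwann cells served as the covariate in turn, 0 brought Scn9a past the threshold, the smallest adjusted p by edgeR being 0.881, which is consistent with differences in neuronal content having widened the spread of Scn9a, whose standard error was 0.25 without a covariate and 0.13 with the pan-neuronal mean. Against a loss of nociceptors, the nociceptor mean differed by 0.13 and Scn9a relative to it by -1.18 (SE 0.13, log2). A shift of Scn9a reads to Scn1a, Scn2a, Scn3a and Scn8a, 4 of its paralogs, was also examined. Their summed CPM at equal pan-neuronal level differed by 3.07 CPM (SE 29.2). Against such a shift, this is less than the 89.2 CPM by which Scn9a differed, a value without that adjustment. A shift of reads to Scn10a and Scn11a cannot be told apart. At equal pan-neuronal level their sum differed by 71.8 CPM (SE 48.0) and Scn10a alone by 64.9 CPM (SE 27.2). An action of the siRNA on Scn9a stays as a hypothesis.

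Nerve injury genes were higher in treated ganglia by camera with the preset correlation, with wide spread, a call lost with an estimated correlation (adjusted p = 0.321) and by fry's directional test (adjusted p = 0.32). A different ratio of neurons to Schwann cells accounts for little, since the difference of the list mean was 0.77 without and 0.73 (SE 0.28) with the pan-neuronal covariate. A single library does not carry all of it, since the difference was 0.55 (SE 0.20) without SCN9A_2544 replicate 4. A chance difference stays open. The exact permutation p of the list mean was 0.0317, or 0.337 adjusted over the lists, an adjustment that no list could pass alone and that therefore decides nothing. A difference in injury by the catheter, which all animals had, or an effect of the siRNA, of any siRNA or of Nav1.7 loss may also contribute and was not tested, as no group here separates them.

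Macrophage markers were higher by camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.473) and by fry's directional test (adjusted p = 0.32). Fry's mixed test passed (adjusted p = 0.047), but it takes changes in either direction and so cannot decide whether the markers were higher. Of the 23 tested markers, 0 belong to another list. The most abundant were Lyz2, at 266 CPM in PBS and 301 CPM in treated ganglia, and Cd74, at 102 and 176 CPM. More blood in the treated ganglia is argued against, since the difference of the list mean was 0.50 without and 0.50 (SE 0.21) with the mean of the neutrophil and erythroid lists as covariate. A lower share of neurons or Schwann cells as the whole cause is argued against, since the difference was 0.55 (SE 0.21) with the pan-neuronal and Schwann cell means as covariates, while the macrophage mean minus the endothelial and fibroblast mean, at 0.35 (SE 0.22), does not decide by itself. A chance difference stays open. The exact permutation p of the list mean was 0.0238, or 0.337 adjusted over the lists, an adjustment that no list could pass alone. A response of macrophages to the siRNA or to injured neurons may contribute and was not tested.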

How the results depend on the processing

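Scaling, filters, robust dispersion and stricter or looser thresholds kept the count of genes called at 0. It was 17 by DESeq2, and 1 each by limma voom with quality weights, with the pan-neuronal covariate, with the Schwann and myelin covariate, with both covariates and without the 3 libraries of lowest pan-neuronal mean. The last 2 were chosen after seeing the data, as were the exact permutation of list means and the fit without mitochondrially encoded genes. The cause of these differences was not tested for DESeq2 and voom. Leaving out 1 library gave 0 to 1 genes. The log2 fold change of Scn9a was -1.14 with the pan-neuronal covariate, -1.16 with the Schwann and myelin covariate and -1.15 with both, each past the threshold (adjusted p of 0.0214, 0.0156 and 0.0314), where its adjusted p ran from 0.0156 to 1 over all alternatives. It ran from -1.14 to -0.85 with 1 library left out. By DESeq2 it was -1.05 with an adjusted p of 0.0576. Relative to pan-neuronal genes the difference ran from -1.28 to -1.08 with 1 library left out. Members of gene lists past the threshold over all genes numbered 6 by DESeq2 and 1 with each of the covariates (pan-neuronal, Schwann and myelin, both).

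Gene lists past the threshold numbered 0 by camera with an estimated correlation, 0 by fry's directional test, 1 by its mixed test (macrophage markers), 0 by exact permutation of list means, 13 by limma voom with quality weights, 8 with both covariates, 16 without the 3 libraries of lowest pan-neuronal mean and 5 to 10 with 1 library left out. The 0 by exact permutation decides little, since no list could pass its adjustment alone. None of the 13 other sodium channel genes was called in any of the 24 alternatives run for them. Same-numbered libraries did not all pair, as the correlations of their deviations were 0.379, 0.005, 0.567, -0.006 and 0.051. For 2 of the 5 the same number was the best match in both directions. Whether this exceeds chance was not tested. With the replicate block edgeR called 0 genes, 8 lists passed, among them pain-related receptors and channels, Schwann cell and adipocyte markers, and Scn9a relative to pan-neuronal genes stood at -1.16 with an exact sign-flip p of 0.0625, the smallest that 5 pairs allow. Simulated changes of 2-fold were recovered at 40% at the depth, spread and number of libraries of these data, which were not varied. That simulation drew genes independently and changed 200 at once.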

Other observations

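Blood genes varied widely between the ganglia without following the groups. The mean of the erythroid and blood genes ran from 3.27 to 6.75 log2 CPM in PBS libraries and from 4.71 to 5.68 in treated libraries. The mean of skeletal muscle markers ran from 1.32 to 3.18 in PBS and from 1.30 to 3.87 in treated libraries, with SCN9A_2544 replicate 1 the highest. Microglial marker Tmem119, placed in the list of central glia, had a log2 fold change of 0.75 and groups that did not overlap, and Hapln2 of the same list had -0.98. By edgeR the adjusted p of Tmem119 was 0.9635 over all genes and 0.0509 adjusted over the list alone. Groups did not overlap for 0.665% of all tested genes, against 0.794% by chance. Among the 17 genes called by DESeq2, 5 were not tested by edgeR because of low counts. The 2 tested genes with a symbol outside the 10 smallest p, named after their values were seen, were Socs3, an inhibitor of cytokine signalling, at 1.26 (SE 0.28), and Tmem126a, a mitochondrial membrane protein, at -0.66 (SE 0.17), both not past the threshold by edgeR.

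A hypothesis chosen after the data were seen was that Penk, which encodes enkephalin precursors, may be raised where Nav1.7 is reduced. The log2 fold change of Penk was -0.18 with a 95% interval of -1.06 to 0.69, which leaves the hypothesis open at this number of libraries.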
